A study of Danio rerio with 9 samples.

How the data were processed

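The series holds RNA sequencing of whole zebrafish embryos at 48 hpf in 3 groups of 3 vials each, exposed from 6 hpf to 10 µM of either compound or to 1% dimethyl sulfoxide. The labels describe the vials as independent biological replicates. Libraries were made from polyadenylated RNA with RNA integrity numbers above 9. Embryos came from group spawns on different days, but nothing ties a replicate number to a day.

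The deposited table gives raw read counts per Ensembl zebrafish gene for each of the 9 libraries, with no normalization. The authors' processing notes name CASAVA 1.8, FastQC, TopHat2, HTSeq and edgeR and the genome build Zv9, without options or order. The strand setting of the counting is not stated, so reads from an overlapping gene on the other strand cannot be told apart. Totals ran from 8106613 to 14435626 reads per library, so that 3 reads, the floor used for a gene without reads, correspond to 0.208 to 0.370 CPM. Such floors cover counting error only.

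Gene symbols were taken by identifier from the reference gene tables. Of 32434 identifiers 20769 had a symbol, of which 10375 were in the capital style of human genes and are printed as given. A symbol was shared by more than 1 gene for 3264 genes, and the identifier is printed where the symbol is ambiguous. Of the 18860 tested genes 3717 (19.7%) had no symbol and were counted but not named, with exceptions that are stated. Of the 1007 genes on the lists 837 were matched by symbol. Where the exact symbol was absent, every gene with the capital symbol left after removing the duplicate suffix was taken. Lists can therefore hold copies that were not listed. For ionocytes, 29 of 32 listed genes were matched, to 45 genes of the table. SLC4A1 (ENSDARG00000012881) thus counts as both a red blood cell and an ionocyte gene.

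Counts were fitted with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM normalization and a quasi-likelihood fit of the 3 group means over all 9 libraries. The fit had 6 residual degrees of freedom and a median prior of 13.79, with a common biological coefficient of variation of 7.23%. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Each group was compared with Control, and BEZO was compared with BaAQ in the same fit. Intervals of the difference between the compounds are 95% intervals from the fit's standard errors and degrees of freedom.

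Before the data were examined, 30 gene lists were fixed, of which 1 enters the counts of lists but is not named or described: the others were aryl hydrocarbon receptor, NRF2 antioxidant, conjugation and transport, red blood cell, iron, myeloid, heart muscle, skeletal muscle, lens, photoreceptor, liver and yolk, exocrine pancreas, neuronal, glia and neural progenitor, cell cycle, heat shock, endoplasmic reticulum stress, sterol, lipid metabolism, hypoxia and glycolysis, cartilage and bone, endothelium, pigment, epidermis, ionocyte, circadian, retinoid, inflammation and mitochondrial genome. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated per list. For each list the members passing over all tested genes and those passing when adjusted over the list alone were counted.

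The rule for naming genes was also fixed before the data were examined. It took, in each comparison, the 10 largest rises and 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and groups that did not overlap. It added up to 4 members of each list with the smallest p past the threshold, and CYP1A1, CYP1B1, cyp1c1, cyp1c2, ahr2, ahrra and ahrrb whatever their p.

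Shared controls were treated by simulating unchanged groups against the same controls 20 times. The fit was tested on simulated data with known changes, where it recovered at least 50.7% of genes changed 1.5-fold, 80.3 to 81.8% of those changed 2-fold and 96.9 to 98.5% of those changed 4-fold, while 2.4 to 7.2% of its calls were genes simulated as unchanged. Among 29 lists drawn at random from all simulated genes, camera with the preset correlation called 0, 2 and 0 in the 3 comparisons. Genes were simulated independently, so this does not measure the error for real lists, whose members may vary together. Alternatives fixed before the data were examined were DESeq2 1.42.0, other size factors, a looser and a stricter filter on low counts, the replicate number as a block, fits of 2 groups, the likelihood ratio test, a stricter threshold, a test against a 1.5-fold change, estimated correlations and each library left out. Thinning all libraries to the smallest total and leaving out the gene with the most reads were added after seeing the data. No sample was left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.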

Results

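Polyadenylated RNA was sequenced from whole zebrafish embryos of the 5D wild-type line at 48 hours post fertilization (hpf). Embryos were held in vials of 20 in 2 mL from 6 to 48 hpf with one of 2 oxygenated polycyclic aromatic hydrocarbons at 10 µM or with the vehicle, 1% dimethyl sulfoxide. BEZO stands for the ketone 1,9-benz-10-anthrone, BaAQ for the quinone benzanthracene-7,12-dione, and Control for the vehicle alone. The labels give 37 °C as the temperature of exposure, which is far above that usual for zebrafish and could not be checked. Each group held 3 vials, and each vial gave 1 library. The Control libraries held 9620666, 14435626 and 13830778 counted reads, the BEZO libraries 11813335, 10925452 and 9656592, and the BaAQ libraries 11351295, 8106613 and 9585311. Of 32434 genes in the table, 4557 had no read in any library and 18860 had enough reads to be tested. Genes with a symbol of the mitochondrial genome took 3.99 to 4.07% of the reads in Control, 3.71 to 3.89% in BEZO and 3.81 to 3.83% in BaAQ. Only 13 of 15 listed mitochondrial genes could be matched by symbol. Mitochondrial transcripts without such a symbol are not in these shares, so the full shares may be higher. Expression is given as CPM, a gene's reads scaled to the total of its library, as mean ± SD over 3 libraries, and log2 fold changes carry their standard error. Positions on the genome are not given, since no annotation of the build used was at hand.

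The comparison of BEZO with Control asks which transcripts the ketone altered by 48 hpf. Genes of the eye were lower, with opn1lw2, a red cone opsin, at 10.56 ± 1.68 CPM in Control and 1.05 ± 0.61 CPM in BEZO (SD, n = 3), and crygm2d11, a gamma crystallin of the lens, at 22.36 ± 4.35 and 2.28 ± 0.46 CPM. Antioxidant genes were higher, among them GSR, glutathione reductase, which rose 2.61-fold. The stress transcription factor gene ATF3 rose 2.35-fold. CYP1B1, a classic target of the aryl hydrocarbon receptor, stood at 6.2 ± 1.29 CPM in Control and 7.35 ± 1.16 CPM in BEZO and did not pass the test. In all, 582 genes were higher and 632 lower at an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), of which 79 and 128 changed more than 2-fold. All 3 libraries of one group lay beyond all 3 of the other for 1202 of these 1214 genes and for 24.71% of all genes tested, where chance gives 10%.

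Lens genes fell as a group, with 26 of 33 measured members lower and none higher (26 and 1 adjusted over the list alone). The median log2 fold change was -0.59, and it was -2.04 ± 0.13 for crygm2d16, -1.62 ± 0.13 for crygm2d15 and -1.38 ± 0.10 for crygm2d17. The crygm2d copies are nearly identical, so their reads may be shared and their individual values are uncertain. Outside that family, 14 of 21 lens members were lower, with a median of -0.43. Photoreceptor genes were lower for 9 of 20 members (14 adjusted over the list alone), and all 20 had negative estimates. Besides opn1lw2 (-3.34 ± 0.25, adjusted p = 2.96e-08), the cone arrestin gene ARR3 fell (-1.76 ± 0.13), as did the recoverin gene rcvrna (-1.82 ± 0.16) and crx, a transcription factor of photoreceptors (-0.71 ± 0.08). Among the genes with the largest falls outside the lists, log2 fold changes were -2.16 for rs1a, the retinoschisin gene, -2.26 for the calcium channel subunit gene CACNA2D4 and -2.79 for the guanylate kinase gene GUK1 (ENSDARG00000005776). The competitive set test (camera) gave adjusted p = 5.09e-48 for the lens list and 7.00e-24 for the photoreceptor list, and 0.029 and 0.0109 with an estimated correlation.

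Among 27 genes of the NRF2 antioxidant response, 9 were higher, 2 lower and 16 did not pass (9 and 3 adjusted over the list alone). GSR rose by 1.39 ± 0.09, prdx1, a peroxiredoxin, by 1.25 ± 0.10 and SQSTM1, the autophagy receptor p62, by 0.83 ± 0.09, whereas TKT, transketolase, fell by 0.64 ± 0.09. The antioxidant list kept its call with an estimated correlation, with adjusted p = 0.025.

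In all, 13 lists passed with the preset correlation and 4 also with an estimated one, with 1 of these not described here; the following 9 passed with the preset correlation alone. Conjugation and transport genes were higher for 5 of 21 members (6 higher and 3 lower adjusted over the list alone), including sult6b1, a sulfotransferase, by 0.88 ± 0.11 and UGT1A1 by 0.80 ± 0.12 (adjusted p = 0.104 with an estimated correlation). Iron genes were higher for 4 and lower for 1 of 17 (the same counts adjusted over the list alone, adjusted p = 0.134 with an estimated correlation), and the ferritin gene fthl27 rose by 0.82 ± 0.08, with reads that may be shared among ferritin copies. Of 25 inflammation genes, 9 were higher (10 adjusted over the list alone, adjusted p = 0.211 with an estimated correlation), among them isg15, an interferon-induced ubiquitin-like gene, by 2.73 ± 0.48 and STAT3 by 0.65 ± 0.11. The Control level of isg15, 0.2 ± 0.1 CPM, was at or below the 3-read floor, so the size of its fold change is uncertain. Myeloid genes were higher for 3 of 20 (3 adjusted over the list alone, adjusted p = 0.143 with an estimated correlation), including CEBPB by 0.81 ± 0.09. Red blood cell genes were lower for 5 and higher for 1 of 26 (8 and 1 adjusted over the list alone, adjusted p = 0.216 with an estimated correlation). The heme synthesis gene alas2 fell by 0.78 ± 0.12, and the embryonic globin gene hbae3, which may share reads with other globins, fell by 0.88 ± 0.12. Cartilage and bone genes were lower for 12 and higher for 3 of 39 (14 and 5 adjusted over the list alone, adjusted p = 0.45 with an estimated correlation), and MATN1, a cartilage matrilin, was at -1 ± 0.18 on the log2 scale. Without BEZO 2 the cartilage list did not pass the test, nor did the iron list without Control 3. Skeletal muscle genes were lower for 4 of 41 (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.347 with an estimated correlation), including myhz1.3, a fast myosin heavy chain. Neuronal genes were lower for 5 of 39 (5 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), with tubb5 at -0.54 ± 0.06 on the log2 scale. Transcripts of the mitochondrial genome were lower for 5 of 13 (7 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), MT-ATP6 among them.

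Aryl hydrocarbon receptor genes did not pass as a group, with 3 higher, 1 lower and 12 not passing (4 and 1 adjusted over the list alone). Within it ahr1b, one of the receptor genes, fell by 0.93 ± 0.10, and ahrrb, the receptor's repressor, was at 0.93 ± 0.55 on the log2 scale with adjusted p = 0.452. The receptor gene ahr2 was higher by 0.27 ± 0.06, a call that ended without BEZO 1, without BEZO 3 or without Control 3. This list could not hold genes without a symbol. ENSDARG00000026039, such a gene singled out after its values were seen, was at 4.61 ± 0.96 CPM in Control and 16.42 ± 1.11 CPM in BEZO. ENSDARG00000058980, chosen in the same way, was at 15.66 ± 0.47 CPM in Control and 34.73 ± 3.55 CPM in BEZO. Whether these genes respond through the receptor was not tested, so the list does not show that no receptor target responded. Genes of the endoplasmic reticulum stress response moved both ways, 8 higher and 8 lower of 27 (9 and 10 adjusted over the list alone). Among those higher, ATF3 rose by 1.24 ± 0.17. For this list, as for the pigment and retinoid lists, the median and the mean or test differed in sign, and none of the 3 passed. Counts higher and lower were 9 and 4 of 33 for epidermis (11 and 5 adjusted over the list alone), 3 and 6 of 31 for liver and yolk (5 and 7), 5 and 0 of 30 for heat shock (5 and 0), 3 and 5 of 29 for pigment (3 and 6) and 4 and 5 of 41 for ionocytes (5 and 5). They were 0 and 2 of 28 for retinoid genes (2 and 3), 2 and 4 of 29 for lipid metabolism (2 and 4), 1 and 1 of 16 for sterol synthesis (1 and 2), 2 and 5 of 35 for circadian genes (2 and 7) and 5 and 2 of 37 for hypoxia and glycolysis (6 and 2). The cell cycle list had 0 and 1 of 30 (0 and 0), heart muscle 1 and 1 of 22 (1 and 2), endothelium 3 and 1 of 26 (4 and 2), glia and neural progenitors 2 and 2 of 19 (3 and 2) and exocrine pancreas 0 and 0 of 6 (0 and 0).

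The number of genes past the threshold was 761 without BEZO 3 and 796 without BEZO 1. In other ways of splitting the same 6 libraries, up to 8 of the 30 lists passed with the preset correlation against 13 here, and 0 with an estimated one against 4. Here and in the comparisons below, such splits mix libraries of both groups, which widens the spread within groups. Their counts are therefore no measure of chance.

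The comparison of BaAQ with Control asks which transcripts the quinone altered. Targets of the aryl hydrocarbon receptor rose, with CYP1B1 at 6.2 ± 1.29 CPM in Control and 78.11 ± 4.85 CPM in BaAQ (SD, n = 3), a 12.5-fold difference, and ahrrb 17.7-fold higher. The ahrrb gene was at 0.19 ± 0.04 CPM in Control and 3.54 ± 0.16 CPM in BaAQ. Its Control level lay below the 3-read floor, so the size of its fold change is uncertain. Antioxidant and conjugating genes rose as well, such as prdx1 by 4.06-fold and sult6b1 by 4.05-fold. FKBP5, a chaperone and textbook glucocorticoid receptor target, fell from 53.62 ± 9.95 to 3.08 ± 1.78 CPM, and 15 of 31 liver and yolk genes and 21 of 39 cartilage and bone genes were lower, although neither list passed with an estimated correlation. In all, 909 genes were higher and 1020 lower (adjusted p under 0.05, edgeR quasi-likelihood, Benjamini-Hochberg), 144 and 106 of them by more than 2-fold. The groups lay apart for 1876 of these 1929 genes and for 27.38% of all genes tested, where chance gives 10%.

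Of 16 aryl hydrocarbon receptor genes, 9 rose, 1 fell and 6 did not pass (12 and 1 adjusted over the list alone). CYP1B1 rose by 3.65 ± 0.12 on the log2 scale (adjusted p = 3.75e-14), ahrrb by 4.14 ± 0.35, sult6b1 by 2.02 ± 0.10 and ahr2 by 0.66 ± 0.06. The gene with the smallest p, ENSDARG00000026039, has no symbol and was singled out after its values were seen: it rose from 4.61 ± 0.96 to 1066.71 ± 46.44 CPM, 230-fold. In BEZO it stood at 16.42 ± 1.11 CPM. ENSDARG00000058980, also without a symbol and singled out after its values were seen, was at 15.66 ± 0.47 CPM in Control. It reached 34.73 ± 3.55 CPM in BEZO and 464.35 ± 20.85 CPM in BaAQ. Lists were matched by symbol, so neither gene could be on one. The symbols CYP1A1, cyp1c1, cyp1c2 and ahrra could not be matched to any identifier of the table, so no value can be given under these names. Their genes may be among the identifiers without a symbol, and they are not shown to be unmeasured. Antioxidant genes were higher for 13 of 27 and lower for none (14 and 2 adjusted over the list alone), with prdx1 at 2.02 ± 0.10, GSR at 1.87 ± 0.09, SQSTM1 at 1.8 ± 0.09 and KEAP1, the sensor that restrains NRF2, at 0.90 ± 0.09. Conjugation and transport genes were higher for 8 and lower for 1 of 21 (9 and 1 adjusted over the list alone), among them gsto2, a glutathione transferase, by 1.51 ± 0.11 and UGT1A1 by 1.23 ± 0.12. Retinoid genes were lower for 5 of 28 and higher for none (6 adjusted over the list alone). Among these were RBP2 (ENSDARG00000093774), a retinol-binding protein gene (-1.05 ± 0.08), LRAT, which esterifies retinol (-1.06 ± 0.17) and ALDH1A2, which makes retinoic acid (-0.55 ± 0.08). These 4 lists kept their call with an estimated correlation, with adjusted p = 0.0011 for both receptor and antioxidant genes, 0.0078 for conjugation and transport and 0.0489 for retinoid genes.

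The remaining 16 of the 20 lists that passed did so with the preset correlation but not with an estimated one, and 1 of these is not described here. Liver and yolk genes were lower for 15 of 31 (17 lower and 1 higher adjusted over the list alone, adjusted p = 0.0755 with an estimated correlation). The angiotensinogen gene agt fell by 1.25 ± 0.10, and APOB, an apolipoprotein of lipid export, fell by 0.96 ± 0.07. Cartilage and bone genes were lower for 21 and higher for 1 of 39 (22 and 2 adjusted over the list alone, adjusted p = 0.121 with an estimated correlation), with COL10A1, a collagen of hypertrophic cartilage, at -1.1 ± 0.11 and acana, an aggrecan, at -0.75 ± 0.09. Pigment cell genes were lower for 11 and higher for 3 of 29 (the same counts adjusted over the list alone, adjusted p = 0.148 with an estimated correlation). OCA2, a melanosome transporter gene, fell by 0.92 ± 0.11, and TYRP1 (ENSDARG00000029204), a melanin synthesis gene, fell by 0.78 ± 0.09. Ionocyte genes were lower for 8 and higher for 1 of 41 (9 and 1 adjusted over the list alone, adjusted p = 0.148 with an estimated correlation). The ammonium transporter genes RHCG and RHBG had log2 fold changes of -3.53 ± 0.58 and -1.27 ± 0.09, and slc12a10.2, a sodium chloride cotransporter gene, of -2.1 ± 0.27.

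Cell cycle genes were lower for 11 of 30 (12 adjusted over the list alone, adjusted p = 0.148 with an estimated correlation), including MCM6, a replication helicase subunit, at -0.60 ± 0.10 and PCNA at -0.47 ± 0.08. Endoplasmic reticulum stress genes were lower for 10 and higher for 3 of 27 (11 and 4 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation). Those lower included the chaperone genes HSP90B1 at -0.84 ± 0.09 and PDIA4 at -0.82 ± 0.09. Heat shock genes were lower for 5 and higher for 3 of 30 (9 and 3 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation), a call that also ended without BaAQ 1, BaAQ 3, BEZO 3, Control 1 or Control 3. Red blood cell genes were higher for 7 of 26 (7 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with alas2 up by 0.60 ± 0.11 and nt5c2l1, a nucleotidase gene, by 1.69 ± 0.16. Iron genes were higher for 5 and lower for 2 of 17 (6 and 2 adjusted over the list alone, adjusted p = 0.121 with an estimated correlation), and fthl27 rose by 1.03 ± 0.08. Inflammation genes were higher for 9 and lower for 3 of 25 (12 and 3 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), where mmp13a, a matrix collagenase, rose by 1.71 ± 0.26 and the complement gene cfb fell by 0.74 ± 0.07. Photoreceptor genes were lower for 5 of 20 (5 adjusted over the list alone, adjusted p = 0.148 with an estimated correlation), ARR3 among them at -0.52 ± 0.12.

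Skeletal muscle genes were lower for 9 and higher for 2 of 41 (14 and 2 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation), with myhz1.3 at -0.47 ± 0.07. Sterol synthesis genes were lower for 3 and higher for 1 of 16 (5 and 1 adjusted over the list alone, adjusted p = 0.148 with an estimated correlation). Lipid metabolism genes were lower for 3 of 29 (4 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation), and this call also ended without BaAQ 3 or Control 2 and with counts thinned to the smallest library, a setting chosen after seeing the data. Mitochondrial genome transcripts were lower for 5 of 13 (8 adjusted over the list alone, adjusted p = 0.2 with an estimated correlation), MT-ND1 at -0.34 ± 0.06. Lists that did not pass were lens, with 0 higher and 3 lower of 33 (0 and 3 adjusted over the list alone), epidermis with 3 and 7 of 33 (9 and 11), myeloid with 3 and 3 of 20 (4 and 4) and circadian with 5 and 2 of 35 (8 and 4). The others were hypoxia and glycolysis with 6 and 6 of 37 (8 and 6), endothelium with 2 and 4 of 26 (3 and 5), heart muscle with 0 and 4 of 22 (0 and 4), neuronal with 0 and 1 of 39 (0 and 1), glia with 0 and 2 of 19 (0 and 2) and exocrine pancreas with 0 and 1 of 6 (0 and 1). For the glia list the median was positive and the mean and the test negative.

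Beyond the lists, log2 fold changes were -4.12 ± 0.37 for FKBP5, -3.18 ± 0.31 for KLF9, a transcription factor gene induced by glucocorticoids, and -2.55 ± 0.26 for the urate oxidase gene uox. The ponzr4 and ponzr3 genes stood at -4.05 ± 0.27 and -3.37 ± 0.27, with reads that may be shared between these copies. The growth factor gene fgf7 rose by 4.07 ± 0.33 and tpmt.2, a methyltransferase gene, by 2.18 ± 0.22. Without Control 3 the number of genes past the threshold was 1276. In other splits of the 6 libraries up to 10 lists passed with the preset correlation against 20 here, and 0 with an estimated one against 4.

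**Figure D1:**
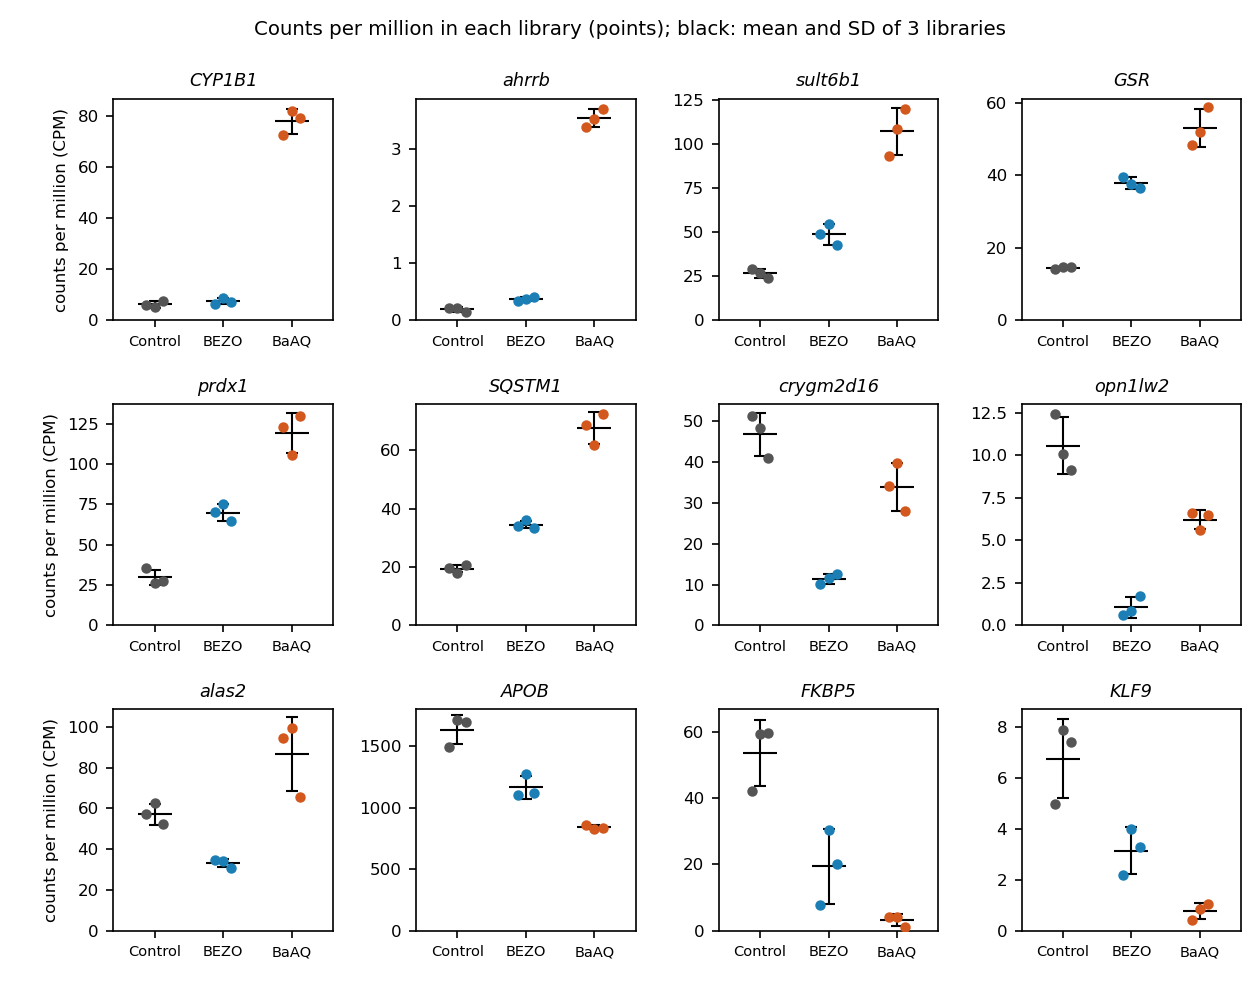
The vertical axes give CPM, from 0, for 12 genes in the 9 libraries (points), with the mean and SD of each group in black. CYP1B1 lies at 78.11 CPM on average in BaAQ against 6.2 CPM in Control and 7.35 CPM in BEZO, and FKBP5 falls from 53.62 CPM in Control to 19.36 CPM in BEZO and 3.08 CPM in BaAQ.

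The comparison of BEZO with BaAQ, at the same concentration and exposure time, asks where a ketone and a quinone of this family differ. Receptor targets differed, with CYP1B1 10.6-fold and ahrrb 9.31-fold lower in BEZO than in BaAQ, and antioxidant genes were also lower in BEZO. Lens, photoreceptor and red blood cell genes were lower in BEZO than in BaAQ, while liver, yolk and epidermal genes were higher. The direct test found 429 genes higher and 483 lower in BEZO than in BaAQ (adjusted p under 0.05, edgeR quasi-likelihood, Benjamini-Hochberg), 44 and 122 by more than 2-fold. The groups lay apart for 895 of these 912 genes and for 22.29% of all genes tested, where chance gives 10%.

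Of the 16 receptor genes, 9 were lower in BEZO than in BaAQ and none higher (10 lower adjusted over the list alone). The log2 difference was -3.41 ± 0.12 for CYP1B1, -3.22 ± 0.32 for ahrrb, -1.14 ± 0.10 for sult6b1 and -0.39 ± 0.06 for ahr2. Antioxidant genes were lower for 8 and higher for 1 of 27 (13 and 1 adjusted over the list alone), with SQSTM1 at -0.97 ± 0.08 and prdx1 at -0.77 ± 0.10. Conjugation and transport genes were lower for 5 of 21 (5 adjusted over the list alone), such as gsto2 at -0.96 ± 0.11. Lens genes were lower in BEZO for 21 of 33 (26 adjusted over the list alone) and photoreceptor genes for 4 of 20 (9 adjusted over the list alone), with crygm2d16 at -1.58 ± 0.13, ARR3 at -1.24 ± 0.14 and opn1lw2 at -2.60 ± 0.28. Red blood cell genes were lower in BEZO for 10 of 26 (10 adjusted over the list alone), with alas2 at -1.38 ± 0.12 and cahz, the red cell carbonic anhydrase, at -0.73 ± 0.09. Liver and yolk genes were higher in BEZO for 12 and lower for 1 of 31 (19 and 3 adjusted over the list alone), epidermal genes for 9 of 33 (12 and 4) and retinoid genes for 5 of 28 (8 and 1). Examples are CP, ceruloplasmin, at 0.92 ± 0.08, the keratin gene krt97 at 0.76 ± 0.06 and RBP2 (ENSDARG00000093774) at 0.42 ± 0.08. All 9 of these lists passed with the preset correlation and with an estimated one, where adjusted p lay between 0.0023 for receptor genes and 0.042 for epidermis.

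A further 11 lists passed with the preset correlation only. Cartilage and bone genes were higher in BEZO for 8 of 39 (10 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation), led by COL10A1 at 1.16 ± 0.11. Ionocyte genes were higher for 9 and lower for 2 of 41 (13 and 2 adjusted over the list alone, adjusted p = 0.0905 with an estimated correlation), with RHBG at 0.91 ± 0.10 and slc12a10.2 at 2.43 ± 0.27. Pigment genes were higher for 5 and lower for 1 of 29 (11 and 1 adjusted over the list alone, adjusted p = 0.0905 with an estimated correlation), OCA2 at 1.00 ± 0.11 among them. Heat shock genes were higher for 10 and lower for 1 of 30 (13 and 1 adjusted over the list alone, adjusted p = 0.131 with an estimated correlation). Endoplasmic reticulum stress genes were higher for 5 of 27 (12 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation), including HSP90B1 at 0.46 ± 0.09. Cell cycle genes were higher for 2 of 30 (6 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), heart muscle genes for 4 of 22 (6 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation) and glial genes for 1 of 19 (3 adjusted over the list alone, adjusted p = 0.224 with an estimated correlation). Myeloid genes were higher for 2 of 20 (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.153 with an estimated correlation), with lyz, lysozyme, at 0.67 ± 0.13. Circadian genes were lower for 3 of 35 (4 adjusted over the list alone, adjusted p = 0.131 with an estimated correlation), rorab at -0.54 ± 0.08 among them, and neuronal genes for 4 of 39 (4 adjusted over the list alone, adjusted p = 0.231 with an estimated correlation). Calls also ended without BEZO 2 or BaAQ 3 for myeloid genes, without BEZO 2, BaAQ 1 or BaAQ 3 for circadian genes, without BEZO 2, BaAQ 1 or BaAQ 2 or with thinned counts for neuronal genes and without BaAQ 2 for heart muscle. Lists that did not pass were inflammation with 3 higher and 1 lower of 25 (3 and 4 adjusted over the list alone), iron with 2 and 1 of 17 (2 and 3) and the mitochondrial genome with 0 and 0 of 13 (1 and 1). Skeletal muscle had 4 and 3 of 41 (6 and 3), lipid metabolism 3 and 1 of 29 (3 and 1), hypoxia and glycolysis 2 and 1 of 37 (2 and 3), endothelium 3 and 2 of 26 (6 and 2), sterol synthesis 1 and 0 of 16 (2 and 0) and exocrine pancreas 1 and 0 of 6 (2 and 0). For the inflammation list the median was negative and the test positive.

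Several genes that changed after both compounds did not pass the test of a difference between them. The log2 difference BEZO minus BaAQ was 0.03 for ATF3 (95% interval -0.30 to 0.36), -0.08 for the glucose transporter gene slc2a3a (-0.24 to 0.07), -0.09 for NR0B2, a nuclear receptor gene (-0.38 to 0.21), and 0.06 for the type I collagen gene col1a1a (-0.08 to 0.20). FKBP5 and KLF9, lower after both compounds, were still 2.63 ± 0.41 and 2.04 ± 0.36 higher on the log2 scale in BEZO than in BaAQ. The count of genes past the threshold was 531 without BEZO 2, and the call for RHCG ended without it. In other splits of the 6 libraries up to 10 lists passed with the preset correlation against 20 here, and 1 with an estimated one against 9.

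**Figure D2:**
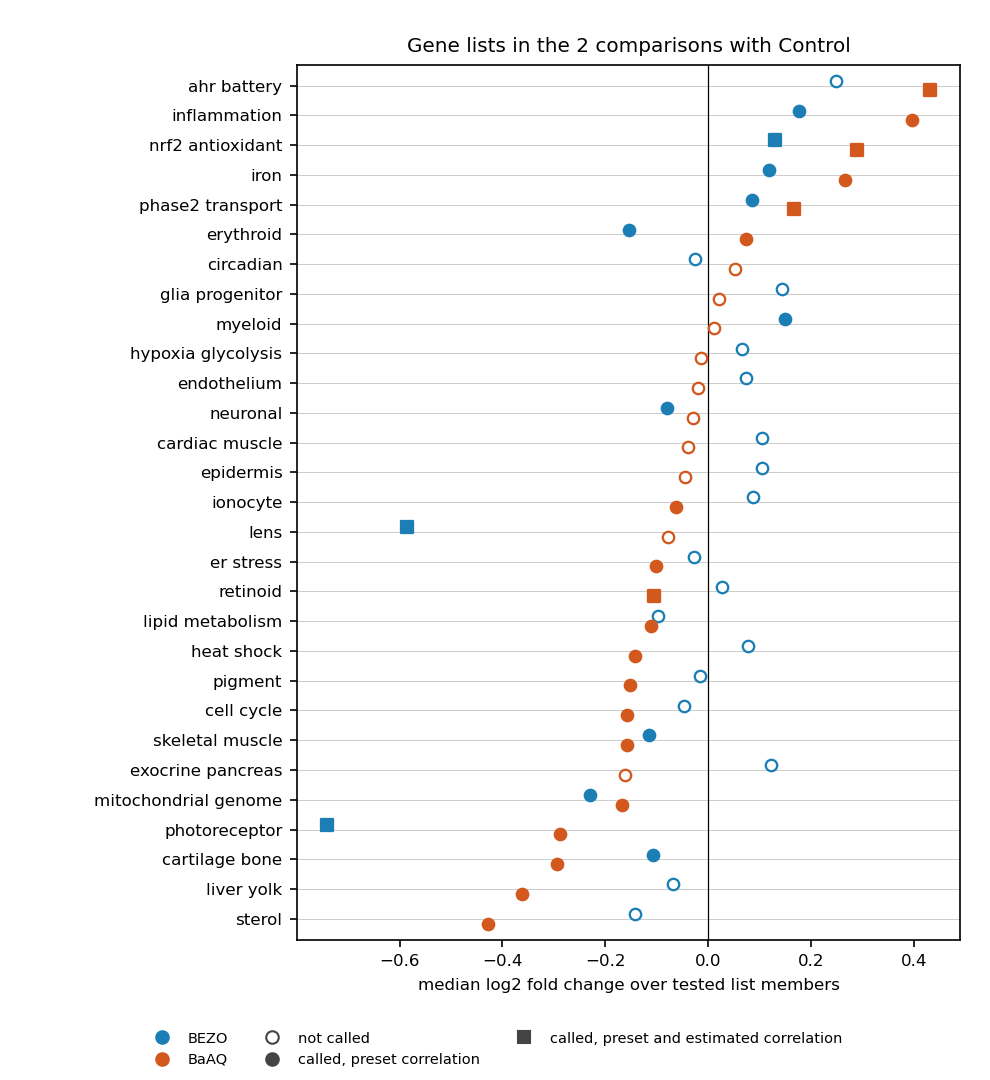
The horizontal axis gives the median log2 fold change of the tested members of each of 29 gene lists against Control, in blue for BEZO and in orange for BaAQ; open circles mark lists that did not pass the camera test, filled circles those that passed with the preset correlation, and squares those that also passed with an estimated one. The lens and photoreceptor lists lie at -0.59 and -0.74 in BEZO, and the receptor list at 0.43 in BaAQ.

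Many genes changed in the same direction after both compounds, among them NR0B2 and slc2a3a, higher after each, and the collagen gene col17a1a and ca2, a carbonic anhydrase of ionocytes, lower after each. In all 302 genes were higher and 282 lower after both, while 16 passed in opposite directions. The 584 shared genes made up 48.1% of the genes changed by BEZO and 30.3% of those changed by BaAQ, and 98 of them differed between the compounds in the direct test. Independent lists of these sizes would share 28.1 higher and 34.2 lower genes and would hold 61.9 in opposite directions. Across the 18860 tested genes, which are not independent replicates, log2 fold changes correlated with Pearson r = 0.547 and Spearman rho = 0.537. Both comparisons used the same Control libraries, and unchanged groups simulated against shared controls 20 times gave a Pearson r of 0.457 to 0.486. The covariance of the log2 fold changes was 0.063, against 0.0173 to 0.0189 in the simulations, so shared controls as simulated gave less than was observed. Genes were simulated independently, so variation that many genes share within a Control vial is not covered. Those simulations shared on average 0.1 higher and 0.2 lower genes. No gene was changed in them, so few could pass in either comparison. These counts therefore cannot show how much of the overlap comes from the shared controls. The controls were too few to be split between the comparisons, so part of the overlap may come from them. Leaving out BEZO 3, Control 2 or Control 3 gave 374, 377 or 382 shared genes.

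**Figure D3:**
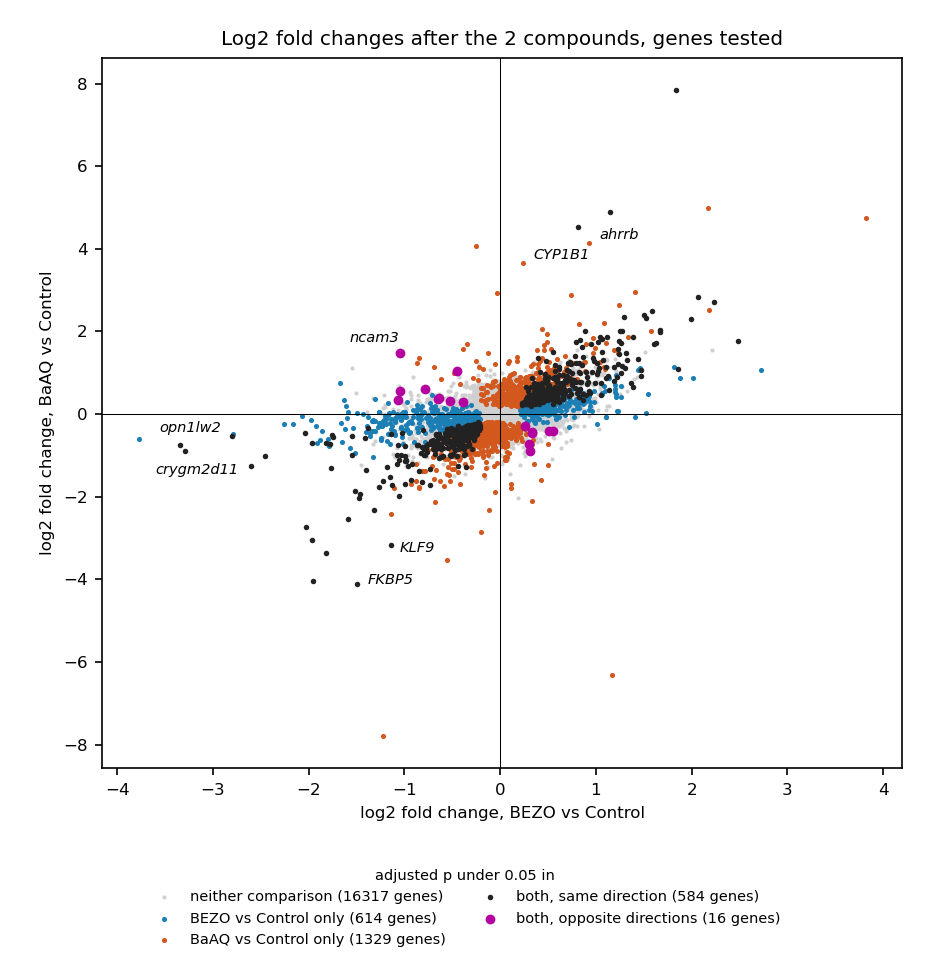
Each point is 1 of 18860 tested genes, with the log2 fold change after BEZO on the horizontal axis and after BaAQ on the vertical axis, coloured by the comparisons in which its adjusted p was under 0.05. The 584 genes that passed in the same direction in both (black) and the 16 that passed in opposite directions (magenta, larger points) are marked, and the points below -6 on the vertical axis are 2 genes without a read in BaAQ, whose fitted values depend on the prior count.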

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

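The choice of the genes below, the tests of scatter and of members outside a gene family for the red blood cell and lens genes, and the counts over other splits of the libraries were written after the results were seen, whereas the 3 comparisons and the lists were fixed before the data were examined. The largest adjusted p of the difference between the compounds among the genes below was 0.000113 (edgeR quasi-likelihood, Benjamini-Hochberg). The genes are here because the compounds moved them in opposite directions against Control, each past the threshold. A small p of the difference therefore largely follows from this choice and is no further support. The log2 difference BEZO minus BaAQ is given for each of the 16 genes.

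Lower after BEZO and higher after BaAQ were 9 genes. Among them were alas2, which starts heme synthesis, at -1.38, the red cell membrane genes epb41b at -1.04 and SLC4A1 (ENSDARG00000012881), the anion exchanger, at -0.84, and si:ch211-250g4.3 at -1.42. The others were the cell adhesion gene ncam3 at -2.53, ENSDARG00000044212 at -1.61, PKHD1L1 (ENSDARG00000091116) at -1.5, the growth arrest gene GADD45G (ENSDARG00000019417) at -1.02 and the semaphorin gene sema6ca at -0.68. Higher after BEZO and lower after BaAQ were 7 genes: SOX9 (ENSDARG00000043923), a cartilage and neural crest transcription factor, at 0.55, the keratin gene krt97 at 0.76, DPYD (ENSDARG00000010267) at 0.8, CP at 0.92, fibronectin FN1 (ENSDARG00000006526) at 0.96, the complement gene cfb at 1.03 and the carboxylate transporter gene SLC13A2 at 1.2. Under 14 other settings, among them each library left out in turn and DESeq2, no sign reversed, and alas2, krt97 and CP alone kept both calls against Control in every setting. A call ended under at least 1 setting for 7 genes after BEZO and for 8 after BaAQ, SLC4A1, epb41b and sema6ca among the latter. The largest adjusted p of these calls was 0.0466, for SLC4A1 after BaAQ. Where a call ended the fold change kept its sign, and it differed from the main value by at most 0.21 on the log2 scale.

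Red blood cell genes moved apart between the compounds, and of 14 such genes written down for this test 8 were lower in BEZO than in BaAQ. These 14 were written down after the results were seen and are no independent support. In the list fixed before, 10 of 26 were lower. Reads shared among globin copies do not account for this on their own, since 6 of the 9 genes other than globins were lower too, with a median log2 difference of -0.73. The log2 fold changes of the 14 genes scattered with a chi-square per degree of freedom of 11.1 after BEZO and 11.6 after BaAQ. They thus did not move by a common amount. A change in the share of red cells would give a common amount only for genes read in no other cells. This was not checked in whole embryos, so the scatter cannot decide on such a change. In BEZO the globin gene hbae3 was at -0.88 while hbbe3 was at 0.60, with reads that may be shared among globins. A change in the share of red cells stays open. Shifts between early and later red cells, or an effect of the compounds on heme genes, stay open too and were not tested.

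Lens genes were lower after BEZO, with a median log2 fold change of -0.59 over 33 members. Reads shared among the crygm2d copies do not account for the whole pattern, since the 21 members outside that family had a median of -0.43 and 14 of them passed. The chi-square per degree of freedom of these 21 members was 7.87, so they did not fall by a common amount. An equal loss of all lens RNA would give a common amount only for genes read in no other tissue. This was not checked in whole embryos, so the scatter cannot exclude such a loss. A delay in development, a smaller or damaged lens with equal or unequal loss, and a direct effect of the compound stay open, since only 1 time point was sampled and no embryo measurements are given. The photoreceptor genes moved in the same direction, which separates none of these.

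Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave a count as large. Every other split mixes libraries of both groups, so a difference between the groups becomes spread within them and lowers the counts. The counts of the other splits are therefore no measure of chance. For genes past the threshold, the real and the highest other counts were 1214 and 1 for BEZO against Control, 1929 and 0 for BaAQ against Control and 912 and 1 for BEZO against BaAQ. For lists with the preset correlation they were 13 and 8, 20 and 10, and 20 and 10, and with an estimated correlation 4 and 0, 4 and 0, and 9 and 1.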

How the results depend on the processing

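Of the settings below, thinning the libraries and leaving out the gene with the most reads were chosen after seeing the data. Counts are given in the order BEZO against Control, BaAQ against Control and BEZO against BaAQ. An adjusted p under 0.01 left 620, 978 and 409 genes, and a test against a 1.5-fold change left 99, 140 and 85, as stricter settings must. Without a filter on low counts 1389 genes differed between BEZO and BaAQ, and the Pearson correlation between the compounds was 0.466; the cause was not tested. An estimated correlation, which allows for members that vary together, left 4, 4 and 9 lists. How much of this loss comes from such members was not tested. With 1 library left out, genes ran from 761 (without BEZO 3) to 1502 (without BaAQ 3), from 1276 (without Control 3) to 1992 (without BEZO 2) and from 531 (without BEZO 2) to 883 (without Control 2). Lists then ran from 13 to 14, 18 to 21 and 17 to 21, shared genes from 374 (without BEZO 3) to 602 and the correlation from 0.489 (without BEZO 1) to 0.588 (without Control 2). With the replicate number as a term (replicate block) 1184, 1916 and 839 genes passed. Residuals of libraries with the same number correlated at -0.036 to 0.029, within the range of other pairs (-0.052 to 0.049). DESeq2 gave 1009, 1571 and 732 genes and thinned libraries 1071, 1682 and 811. No call among the 350 of genes named by rule reversed its direction under any setting run. The same held for lists that passed in the main fit or under the setting. Lists that passed in neither were not checked for a change of direction. Of the 350 calls, 324 of the 341 with a DESeq2 value were kept, 341 with the replicate block and 98 in the test against a 1.5-fold change. At this depth a 1.5-fold change was recovered in simulations for as few as 50.7% of genes, so a gene that did not pass is not shown to be unchanged.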

Other observations

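The test of glucocorticoid receptor targets, the count of genes that set a library apart and the choice of the genes named in this part were made after the results were seen, whereas the comparisons that give their values were fixed before. Of the endoplasmic reticulum stress list, the chaperone genes HSP90B1 and PDIA4 were lower after BEZO at -0.38 and -0.42 and lower still after BaAQ at -0.84 and -0.82 (for PDIA4 the difference did not pass without BEZO 2), while ATF3 was higher at 1.24 and 1.2 and sesn2 at 1.37 and 0.75. TRIB3 and CHAC1, which belong to the amino acid response, passed after BEZO at 0.51 and 0.62 and did not after BaAQ at 0.18 and 0.20. Their differences between the compounds, 0.33 and 0.42, passed, but both ended with DESeq2, with only these 2 groups in the fit and without BEZO 2, BaAQ 1 or BaAQ 2. That of TRIB3 also ended without BaAQ 3 and with thinned counts, a setting chosen after seeing the data.

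The heat shock list did not pass between the compounds with an estimated correlation (adjusted p = 0.131). Of its members, hsp70l rose by 0.94 after BEZO and was at 0.29 after BaAQ (difference 0.64, adjusted p = 0.033, edgeR quasi-likelihood), whereas hsp90aa1.1, a chaperone of muscle, fell by 0.97 after BaAQ. The hspb9 gene rose by 1.16 after BaAQ. Copies of hsp70 are near identical, so the value of a single copy is uncertain.

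The library BaAQ 3 differed from the other BaAQ libraries with a chi-square per degree of freedom of 8.91 and 7.01, against 2.16 between BaAQ 1 and BaAQ 2. The value was 6.68 between Control 2 and Control 3, but this measure is taken against counting noise and grows with the number of reads, which was largest in those 2 libraries. Of genes with at least 10 CPM on average in BaAQ, 6 lay 2-fold or more above both other libraries in BaAQ 3, against 0 or 1 for any other library within its group. Muscle genes were among the 6: actc1c was at 81.08 CPM there against 15.11 and 16.54 CPM, and TTN (ENSDARG00000000563), titin, at 10510 CPM against 4830 and 4712 CPM. Neither passed the test between BaAQ and Control. Without BaAQ 3 the number of genes changed by BEZO was 1502.

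FKBP5 and KLF9 are textbook targets of the glucocorticoid receptor, and a candidate explanation of their fall after BaAQ is a general loss of expression of its targets. The test took 12 other textbook genes written down for it, of which none passed as lower and 1, PCK1, passed as higher (0.57), with a median log2 fold change of -0.05. Estimates were below 0 for 6 of the 12, the lowest -0.81 for a copy of PER1 (ENSDARG00000056885, adjusted p = 0.0571, edgeR quasi-likelihood). These values speak against a loss shared by all targets, while a change limited to a few targets, or a cause other than this receptor, stays open.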
